A study of Escherichia coli DH1 with 6 samples.

How the data were processed

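Gene expression was measured on single-colour NimbleGen oligonucleotide arrays (Cy3 label) in 6 samples of *Escherichia coli* DH1, a laboratory strain of the K-12 lineage. Cultures in M9 minimal medium with glucose and casamino acids were grown to mid-log phase and then held for 1 h with 0% or 6% 1,4-butanediol, a short-chain diol used as an industrial chemical. Each group has 3 arrays, which the labels call technical replicates. The labels do not say whether the arrays of a group came from separate cultures, RNA preparations or labelling reactions. All p-values below therefore measure the spread between these arrays, which may be purely technical, and not the spread between independent cultures.

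The deposited values are 1 intensity per gene and array on a linear scale, made by the authors with RMA, per the submitters' processing notes. RMA corrects the background, normalizes between arrays and summarises the probes of a gene. The software and settings are not given in the sources used here. Each array file holds 4254 genes and 1 row for probes of random sequence. Of the genes, 4249 have 16 probe pairs, and the random row summarises 4013 probes, per the file headers. The value table of the whole series holds the same intensities without the random row, with a largest absolute log2 difference of 0. RMA leaves an additive background in dim values, so fold changes of genes close to the random probes can be understated. The number of arrays limits the precision, and the files give no detection call.

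The deposited intensities were converted to log2 and used with no further normalization. Locus tags were paired with symbols through a reference gene table of the K-12 strain MG1655: 4243 of 4254 matched, and the other 11 are named by locus tag. Coordinates are those of the array annotation inside the files, on its version of the K-12 chromosome. They refer to coding sequences. The image names inside the files were read as slide, position on it and photomultiplier setting (scanner gain). Neither the labels nor the file headers state this reading, and every result with slide as a block or at equal gain rests on it. By this reading, slide 1 holds the 3 control arrays and 6% replicate 1. Slide 2 holds 6% replicates 2 and 3. The gain was 425 for control replicates 1 and 2 and 6% replicate 1, 410 for control replicate 3, 400 for 6% replicate 2 and 460 for 6% replicate 3.

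The comparison of 6% with 0% was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 over all 6 arrays, without covariates, with two-sided p-values adjusted by the Benjamini-Hochberg method over all genes. A gene was called when its adjusted p was under 0.05 and its fold change at least 2. Only called genes are described as having risen or fallen. Levels are given as the mean log2 intensity ± SD of 3 arrays, and log2 fold changes as 6% minus 0% ± SE. The 35 gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over the 35 lists, and again with the correlation estimated per list. The second setting also takes its degrees of freedom from the 6 arrays and not from the number of genes. A list can therefore lose its call there even where its estimated correlation is low. Camera compares a list with all other genes. The rotation test fry, which asks whether the genes of a list move one way on balance, was an alternative. Lists overlap, and members of 1 operon are not independent. Of the list symbols, 1 (csbD) had no match and 6 were matched through synonyms.

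The test, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 10 largest rises and 10 largest falls among called genes whose 6% arrays all lie on one side of the 3 control arrays, and up to 3 called members per list with the largest change (or, with none called, the member with the largest change). It yields 100 genes, of which 98 are called. Genes named outside the rule are said to have been chosen after their values were seen. The alternatives were the replicate number as a block, slide as a block, the series value table, quantile, median, cyclic loess and reference-gene scaling, a filter on the dimmest 25% of genes, other variance settings, array weights, other fold thresholds and leaving out each array. Slide 2 holds only 6% arrays, so the fold change with slide as a block equals the difference of 6% replicate 1 from the mean of the 3 controls.

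The fit was tested on simulated data for 6% against 0%, with 4254 genes at the measured mean levels and spreads drawn from limma's fitted prior and 200 genes changed. It called 97.0% of genes changed 4-fold and 28.5% of genes changed 2-fold, with false shares of 1.02% and 4.76% among genes past the adjusted p. A 2-fold simulated fall of the ribosomal protein list was called with 0 of the other lists at adjusted p under 0.05. The shares above and this 0 hold for the simulated values only. Weights estimated for the measured arrays ran from 0.22 on 6% replicate 3 to 4.54 on 6% replicate 1, so the arrays were not equally precise. In the measured data the estimated correlation within a list reached 0.76, and other splits of the 6 arrays gave up to 16 lists.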

Results

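The response of *E. coli* DH1 to 6% 1,4-butanediol for 1 h was measured on 6 arrays, 3 of unexposed cells (0%) and 3 of exposed cells. Median intensity over the 4254 genes was between 174 and 193 on every array. The random-sequence probes read 58.5, 79.1 and 65.8 on the 0% arrays and 52.4, 48.5 and 72.4 on the 6% arrays. Between 21.2% and 44.1% of genes lay within 2-fold of these probes on any one array. Pearson's r across genes was between 0.951 and 0.976 within the 0% arrays, between 0.896 and 0.982 within the 6% arrays and between 0.796 and 0.872 across the groups. The first principal component, with 63.0% of the variance, separated the groups. The second, with 24.96%, set 6% replicate 3 and control replicate 2, the arrays with the narrowest range in each group, apart from the other 4. Across genes, the deviations of these 2 arrays from their group means correlated at r = 0.59. The interquartile range of log2 values was narrowest on 6% replicate 3, at 1.47, against 1.92 and 1.94 on the other 6% arrays. It was 2.37 and 2.15 on control replicates 1 and 3, wider than on any 6% array, and 1.87 on control replicate 2. The deposited values therefore still differ in range between arrays.

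The comparison asked which genes of DH1 were expressed differently after exposure to 6% 1,4-butanediol. As lists, histidine biosynthesis (8 of 8 genes called), arginine biosynthesis (10 of 12), ribosomal proteins (31 of 54), heat shock chaperones and proteases (9 of 21) and acid resistance (8 of 18) were lower at 6%, and methionine biosynthesis (5 of 12) was higher. None of these list calls held with an estimated correlation (adjusted p = 0.34 for the lower lists and adjusted p = 0.39 for methionine with an estimated correlation). Among single genes, the biotin synthase gene bioB and the transporter gene yhjX rose. Of 4254 genes, 259 rose and 336 fell at least 2-fold at an adjusted p under 0.05 (limma). Without the fold threshold, 447 were higher and 521 lower. Those last counts were 215 and 263 without control replicate 1, 247 and 344 without control replicate 3, 261 and 374 without 6% replicate 1, and 261 and 364 without 6% replicate 2. With slide (as read from the image names) as a block, which leaves 6% replicate 1 as the only exposed array on the controls' slide, 62 genes rose and 93 fell, of which 61 and 93 were among the calls above. All 595 called genes had the same sign of change on that array, and 220 of the 259 and 267 of the 336 differed there by at least 2-fold. That array is 1 of the 3 exposed arrays that made the calls, so a shared sign was likely beforehand and is no independent support. Fold changes varied with level: in 10 bins of genes by brightness, the median log2 fold change was highest in bin 4 (0.14) and lowest in bin 9 (-0.35). Calls numbered 278 higher and 275 lower after quantile normalization and 297 and 269 after cyclic loess. The excess of falls was therefore lost under these normalizations. It remained after centring each array on its median (215 and 368). Centring each array on the reference genes cysG, hcaT and idnT moved the median log2 fold change of all genes from 0.02 to -0.28 and the calls to 141 higher and 618 lower. None of the 595 called genes changed sign under this or any other alternative that kept the gene in the fit. The reference-gene shift is smaller than a 2-fold change, so it could turn the sign of no called gene. All alternatives reuse the same arrays, so the constant signs are no separate support for the calls.

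**Figure D1:**
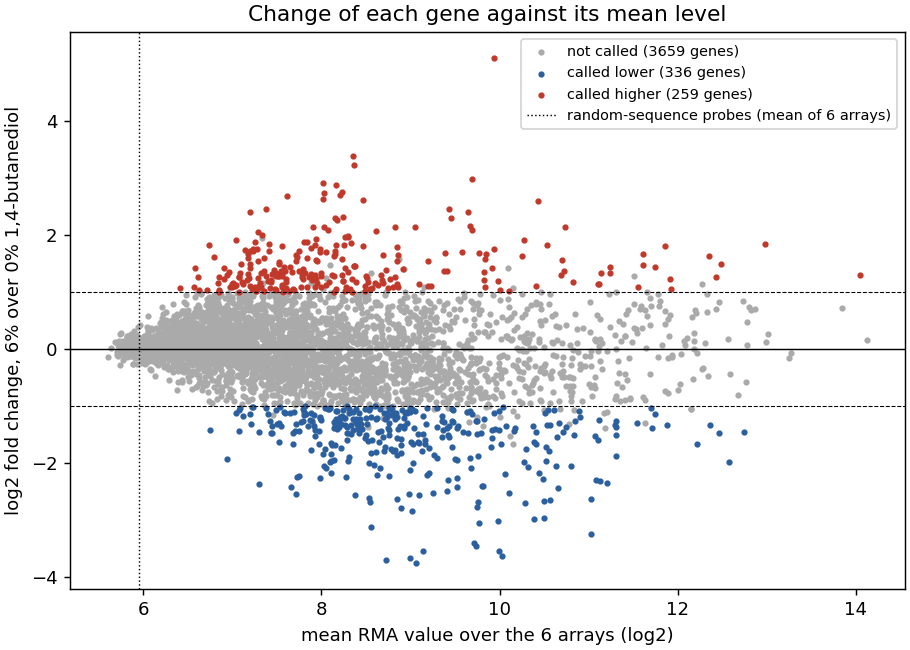
Log2 fold change of each gene (6% over 0% 1,4-butanediol) against its mean log2 RMA value over the 6 arrays, 1 point per gene, with dashed lines at a 2-fold change and a dotted line at the random-sequence probes. The 259 called rises are red and the 336 called falls blue, and yhjX, at 5.10, is the highest point.

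The strongest rise was that of yhjX (b3547), a predicted transporter gene at 3708822 to 3710030, from 7.38 ± 0.49 to 12.5 ± 0.46 (SD, n = 3), a log2 fold change of 5.10 ± 0.31 (34.4-fold, adjusted p = 3.2e-05). Next came the short genes yicT (3834448 to 3834579, 10.4-fold) and ydgU (1669801 to 1669884, 9.37-fold), the predicted gene ybiJ (836888 to 837148, 7.84-fold) and yecR (7.54-fold). The biotin synthase gene bioB (808567 to 809607) rose 7.32-fold, from 6.73 ± 0.16 to 9.60 ± 0.32. The others of the 10 largest rises were the e14 prophage gene ymfQ (6.76-fold), b4591 (6.65-fold), the phage shock gene pspG (6.46-fold) and yfjZ, a prophage antitoxin gene (6.43-fold). Of these 10, 8 lay within 2-fold of the random probes at 0%, where folds can be understated; yhjX and ybiJ did not. Of the 10, 9 kept their call with slide as a block, and yfjZ had a log2 fold change of 3.25 with an adjusted p of 0.053.

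The strongest fall was that of glnQ (b0809, 844964 to 845686), a subunit of the glutamine transporter, from 10.9 ± 0.18 to 7.18 ± 0.17 (SD, n = 3), a log2 fold change of -3.75 ± 0.20 (13.5-fold lower, adjusted p = 3.2e-05). Among the 10 largest falls, 5 belonged to the hya genes of hydrogenase 1: hyaE (13.0-fold), hyaD (12.6-fold), hyaB (11.6-fold), hyaA (10.5-fold) and hyaF (8.67-fold), which lie between 1031362 and 1036829. The histidine biosynthesis genes hisF (2093868 to 2094644, 12.3-fold), hisC (11.6-fold) and hisI (9.43-fold) completed the 10 together with the ribosomal protein gene rplI (4424131 to 4424580), whose log2 fold change was -3.46 ± 0.20. All 10 kept their call with slide as a block.

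**Figure D2:**
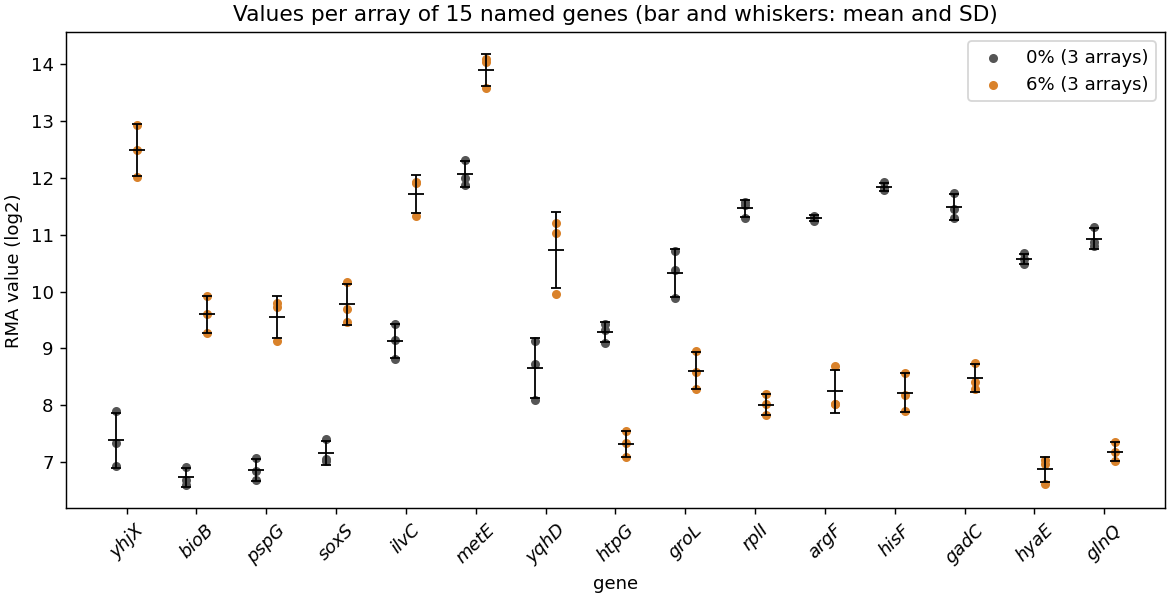
Log2 RMA values of 15 genes on each of the 3 arrays at 0% (grey) and at 6% (orange), with the mean and SD of each group. In each gene shown, the 3 arrays of one group lie apart from the 3 of the other; yhjX moves from 7.38 to 12.5 and glnQ from 10.9 to 7.18.

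Amino acid biosynthesis genes moved in different directions by pathway. All 8 histidine biosynthesis genes fell, with a median log2 fold change of -2.96, and 8 of 8 did so when adjusted over the list alone. Camera gave the list an adjusted p of 3.4e-10 (adjusted p = 0.34 with an estimated correlation). Of 12 arginine biosynthesis genes, 10 fell and none rose (10 when adjusted over the list alone), with a median of -2.02. These included argF (8.29-fold lower), argC (6.07-fold) and argH (5.83-fold). They also included artJ, an arginine transporter subunit gene that the list holds beside the biosynthesis genes. The camera adjusted p was 3.5e-10 (adjusted p = 0.34 with an estimated correlation). argF and argI encode closely related ornithine carbamoyltransferases, so their probes may not tell them apart. Of 18 tryptophan and aromatic pathway genes, 9 fell (9 when adjusted over the list alone), with a median of -0.94. They included trpE (4.49-fold), trpB (4.23-fold) and aroF (3.98-fold), which encodes the first enzyme of the common aromatic pathway. The list's adjusted p was 1.8e-05 (adjusted p = 0.34 with an estimated correlation). Methionine biosynthesis rose as a list: 5 of 12 genes rose and none fell (6 when adjusted over the list alone), with a median of 1.06. metL (3.77-fold), metE (3.56-fold), the cobalamin-independent methionine synthase gene, and metB (3.18-fold) led it. Its adjusted p was 1.0e-04 (adjusted p = 0.39 with an estimated correlation). On the fit with slide as a block, 8 histidine, 9 arginine and 0 aromatic genes fell and 3 methionine genes rose, and the medians were -2.63, -2.05, -0.56 and 1.38.

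The branched-chain and sulfur pathways did not pass the camera test; fry called the branched-chain list higher (adjusted p = 0.015). Of 14 leucine, isoleucine and valine genes, ilvC, a ketol-acid reductoisomerase gene, rose 6.01-fold (adjusted p = 2.6e-04) and ilvN rose 2.68-fold. The median was 0.02, between -0.0064 and 0.17 on leaving out 1 array, and the camera adjusted p was 0.41. Of 16 sulfate assimilation and cysteine genes, 2 fell, led by the sulfate transporter gene sbp (4.64-fold lower). The camera adjusted p was 0.77, toward lower values while the median was 0.06, or -0.24 without 6% replicate 1 (adjusted p = 0.061), -0.02 without control replicate 2 and 0.20 without 6% replicate 3. The shift was the other way with slide as a block, with a median of 0.54 and an adjusted p of 0.012. Of 24 purine and pyrimidine genes, purA (2.53-fold) and pyrB (2.18-fold, within 2-fold of the random probes at 0%, where folds can be understated) rose and 1 fell, with a median of -0.41 and an adjusted p of 0.11. That list passed the test, toward lower values, without 6% replicate 3 (adjusted p = 0.038) and with slide as a block (adjusted p = 0.040), and not without any other single array (adjusted p up to 0.27).

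Ribosomal protein genes were lower at 6%: 31 of 54 fell and none rose (35 lower and 1 higher when adjusted over the list alone). The median log2 fold change was -1.34, and 53 of 54 were negative. rplI, rpsP (6.50-fold) and rplS (5.74-fold), a gene of the same operon as rpsP, fell furthest. The 1 positive member was rplJ, at 1.00 ± 0.34 (adjusted p = 0.064), named after its value was seen. Camera gave the list an adjusted p of 1.2e-17 (adjusted p = 0.34 with an estimated correlation). Of the 54, 12 fell with slide as a block, with a median of -1.12. Of 16 cold shock and RNA helicase genes, 5 fell. cspB, a cold shock protein gene, fell from 7.91 ± 0.51 to a level within 2-fold of the random probes, so that its fold is not given, and infB, the gene of translation initiation factor 2, fell 3.01-fold. The list's adjusted p of 0.038 (adjusted p = 0.51 with an estimated correlation) became 0.075 without control replicate 1, 0.056 without control replicate 3, 0.30 without 6% replicate 3 and 0.14 with slide as a block.

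Of 21 heat shock chaperone and protease genes, 9 fell, 12 were not called and none rose (11 lower when adjusted over the list alone), with a median of -1.05 and an adjusted p of 8.9e-05 (adjusted p = 0.34 with an estimated correlation). The largest falls were those of htpG, a chaperone of the HSP90 family (3.90-fold), and of the chaperonin genes groS (3.35-fold) and groL (3.29-fold). dnaK had a log2 fold change of -1.33 ± 0.29 (adjusted p = 0.012) and also fell, whereas the small heat shock genes ibpA (-0.48 ± 0.25, adjusted p = 0.21) and ibpB (0.30 ± 0.23, adjusted p = 0.42) were not called. These last 3 genes were named after their values were seen. Only 2 members, htpG among them, fell with slide as a block, with a median of -0.75.

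Of 16 sigma-E envelope stress genes, 2 fell, among them the lipid A biosynthesis gene lpxD (2.26-fold). Camera gave an adjusted p of 0.16, or 0.028 without control replicate 2 and 0.68 without 6% replicate 3. Of 18 Cpx and Bae genes, cpxP, a periplasmic regulator of the Cpx system, rose 2.41-fold, and the list's adjusted p was 0.77. Of 7 phage shock genes, pspG rose and 1 fell, with a median of 0.53 and a camera adjusted p of 0.084, while fry called the list higher (adjusted p = 0.0063). Of 26 peroxide and superoxide genes, soxS, the activator of the superoxide response, rose 6.14-fold, from 7.16 ± 0.21 to 9.77 ± 0.36 (adjusted p = 2.1e-04). By contrast 3 fell, sufE (2.75-fold) and acnA (2.53-fold) furthest. This list's adjusted p of 0.038 toward lower values (adjusted p = 0.54 with an estimated correlation) became 0.12 without control replicate 1, 0.22 without 6% replicate 3, 0.059 after centring on the reference genes and 0.25 with slide as a block. Of 24 efflux and regulator genes, 3 rose, soxS and marB (4.40-fold), a gene of the multiple antibiotic resistance operon, furthest. 2 fell, mdtE, an efflux pump gene, furthest (4.74-fold). The median was 0.10, between 0.04 and 0.16 on leaving out 1 array and -0.21 after centring on the reference genes. Camera gave the list an adjusted p of 0.41, and fry called it higher (adjusted p = 0.013). Of 20 SOS genes, 2 fell, yebG (2.32-fold) furthest, with a list adjusted p of 0.45. In this group of lists, soxS, pspG, marB and mdtE kept their call with slide as a block.

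Of 18 acid resistance genes, 8 fell and 1 rose (10 and 1 when adjusted over the list alone), with a median of -1.20 and an adjusted p of 0.0020 (adjusted p = 0.34 with an estimated correlation). The glutamate antiporter gene gadC fell 8.07-fold, the glutamate decarboxylase gene gadB 6.26-fold and the lipoprotein gene slp 4.79-fold. The list's median was -0.77 without 6% replicate 3 (adjusted p = 0.010). gadA and gadB are near-identical, so their probes may not tell them apart. Among the 18, 4 fell with slide as a block, gadC and gadB among them, with a median of -0.99. Of 20 general stress genes of the RpoS regulon, 3 fell and yciG rose 2.51-fold. This list had an adjusted p of 0.099, and it passed toward lower values without 6% replicate 1 (0.044) and without 6% replicate 2 (0.016). Its median of -0.40 became -0.10 without 6% replicate 3 (adjusted p = 0.72) and -0.09 with slide as a block (adjusted p = 0.53), and without control replicate 1 the adjusted p was 0.37. Of 16 osmoprotectant genes, proW, a subunit of the glycine betaine transporter, rose 4.18-fold (adjusted p = 0.0011) and 1 fell. The list's median was 0.16, or 0.04 without control replicate 1, -0.02 without 6% replicate 3, -0.04 with slide as a block and -0.15 after centring on the reference genes, and its adjusted p was 0.79. proW kept its call with slide as a block.

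Genes of energy metabolism that changed were mostly lower. Of 21 aerobic respiratory chain genes, 8 fell and none rose, with a median of -0.57 and an adjusted p of 0.0020 (adjusted p = 0.34 with an estimated correlation). The falls included nuoE (3.75-fold), nuoG (3.47-fold) and nuoF (3.21-fold), subunits of NADH dehydrogenase I, of which nuoG and nuoF kept their call with slide as a block. Of 32 fermentation and anaerobic respiration genes, 8 fell and 1 rose, with a median of -0.62 and an adjusted p of 0.011 (adjusted p = 0.34 with an estimated correlation). The fumarate reductase gene frdC fell 3.10-fold and pta, the phosphate acetyltransferase gene, 2.86-fold. Neither gene kept its call with slide as a block, at log2 fold changes of -1.23 and -0.84, and the list median there was -0.57. Of 9 ATP synthase genes, 3 fell, atpG (2.60-fold) furthest, and the list's adjusted p was 0.028 (adjusted p = 0.55 with an estimated correlation). Of 18 glycolysis genes, 3 fell, pfkB (2.68-fold) furthest, and the list's adjusted p was 0.018 (adjusted p = 0.71 with an estimated correlation). The ATP synthase and glycolysis lists had adjusted p-values of 0.072 and 0.075 without control replicate 1, 0.28 and 0.51 without 6% replicate 3, and 0.37 and 0.53 with slide as a block. Their medians, -0.67 and -0.54 over all arrays, were -0.27 and -0.20 without 6% replicate 3 and -0.03 and -0.04 with slide as a block, and that of ATP synthase was -1.04 without 6% replicate 1. Of 18 TCA cycle genes, 2 fell, acnA furthest, with a list median of -0.00081 (between -0.13 and 0.08 on leaving out 1 array) and an adjusted p of 0.77. The largest change on that list was positive, a log2 fold change of 1.94 in a gene that was not called.

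Lipid and surface genes showed few calls. Of 18 fatty acid synthesis genes, 4 fell and none rose, with a median of -0.51. The list's adjusted p of 0.016 (adjusted p = 0.55 with an estimated correlation) became 0.21 without 6% replicate 3 and 0.21 with slide as a block. None of 10 fatty acid degradation genes was called by limma, and 2 had an unadjusted p under 0.05. fadE, the acyl-CoA dehydrogenase gene, had the largest change, at 0.47 ± 0.21 (adjusted p = 0.14) and within 2-fold of the random probes at 0%, and the list's adjusted p was 0.77. Of 21 outer membrane genes, ompW (4.24-fold) and the porin gene ompC (3.15-fold) fell, with a list adjusted p of 0.29. Only ompW kept its call with slide as a block. None of 43 flagella and chemotaxis genes was called by limma, and 6 had an unadjusted p under 0.05. The hook-length gene fliK had the largest change, at 0.81 ± 0.20 (adjusted p = 0.021), also within 2-fold of the random probes at 0%. The flagella list had a median of 0.13, or -0.17 after centring on the reference genes, and an adjusted p of 0.084. It passed toward higher values without control replicate 2 (0.011), without 6% replicate 1 (0.047) and without 6% replicate 2 (0.015), whereas the median was -0.01 without 6% replicate 3 (adjusted p = 0.68) and -0.01 with slide as a block. Of 26 curli, fimbriae and colanic acid genes, 4 fell, including the type 1 fimbria gene fimH (2.33-fold), and 1 rose, with an adjusted p of 0.79 for the list.

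Of 52 secondary sugar genes, 5 rose and none fell, with a median of 0.24 and an adjusted p of 0.018 (adjusted p = 0.34 with an estimated correlation). srlA, a sorbitol transporter gene, rose 5.44-fold, rbsD 3.21-fold and malG 2.53-fold. The adjusted p became 0.052 without 6% replicate 1, and the median became -0.06 after centring on the reference genes. Of 21 metal transport genes, 2 rose, the manganese transporter gene mntH (2.72-fold) furthest, with a median of 0.32, or 0.01 after centring on the reference genes and 0.50 without 6% replicate 1. Their adjusted p was 0.018 (adjusted p = 0.34 with an estimated correlation). Of 33 iron uptake genes, 3 rose and 2 fell. Among them the iron-dicitrate transporter gene fecD rose 2.48-fold and entA and exbD fell 2.49-fold and 2.40-fold. Camera gave an adjusted p of 0.72. Of the genes named here, srlA kept its call with slide as a block.

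Of 23 alcohol and aldehyde oxidoreductase genes, 2 rose and 1 fell. yqhD, an NAD(P)-dependent alcohol dehydrogenase gene at 3153377 to 3154540, rose 4.24-fold, from 8.65 ± 0.53 to 10.7 ± 0.68 (adjusted p = 0.0051), and dkgB, an aldo-keto reductase gene, rose 3.23-fold. gabD, the succinate-semialdehyde dehydrogenase gene, fell 2.79-fold. The list's median was 0.13, between 0.04 and 0.17 on leaving out 1 array and -0.18 after centring on the reference genes, and its adjusted p was 0.72. In the list for putrescine and 4-aminobutyrate degradation, gabT (3.46-fold) and gabD fell and the other members of 15 were not called, with an adjusted p of 0.79. yqhD kept its call with slide as a block and dkgB, gabD and gabT did not, at adjusted p-values of 0.060, 0.086 and 0.063. Of 27 prophage genes, 3 rose, among them relB, the antitoxin gene of the Qin prophage (3.39-fold), and essD (2.18-fold, within 2-fold of the random probes at 0%), with an adjusted p of 0.76 for the list.

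**Figure D3:**
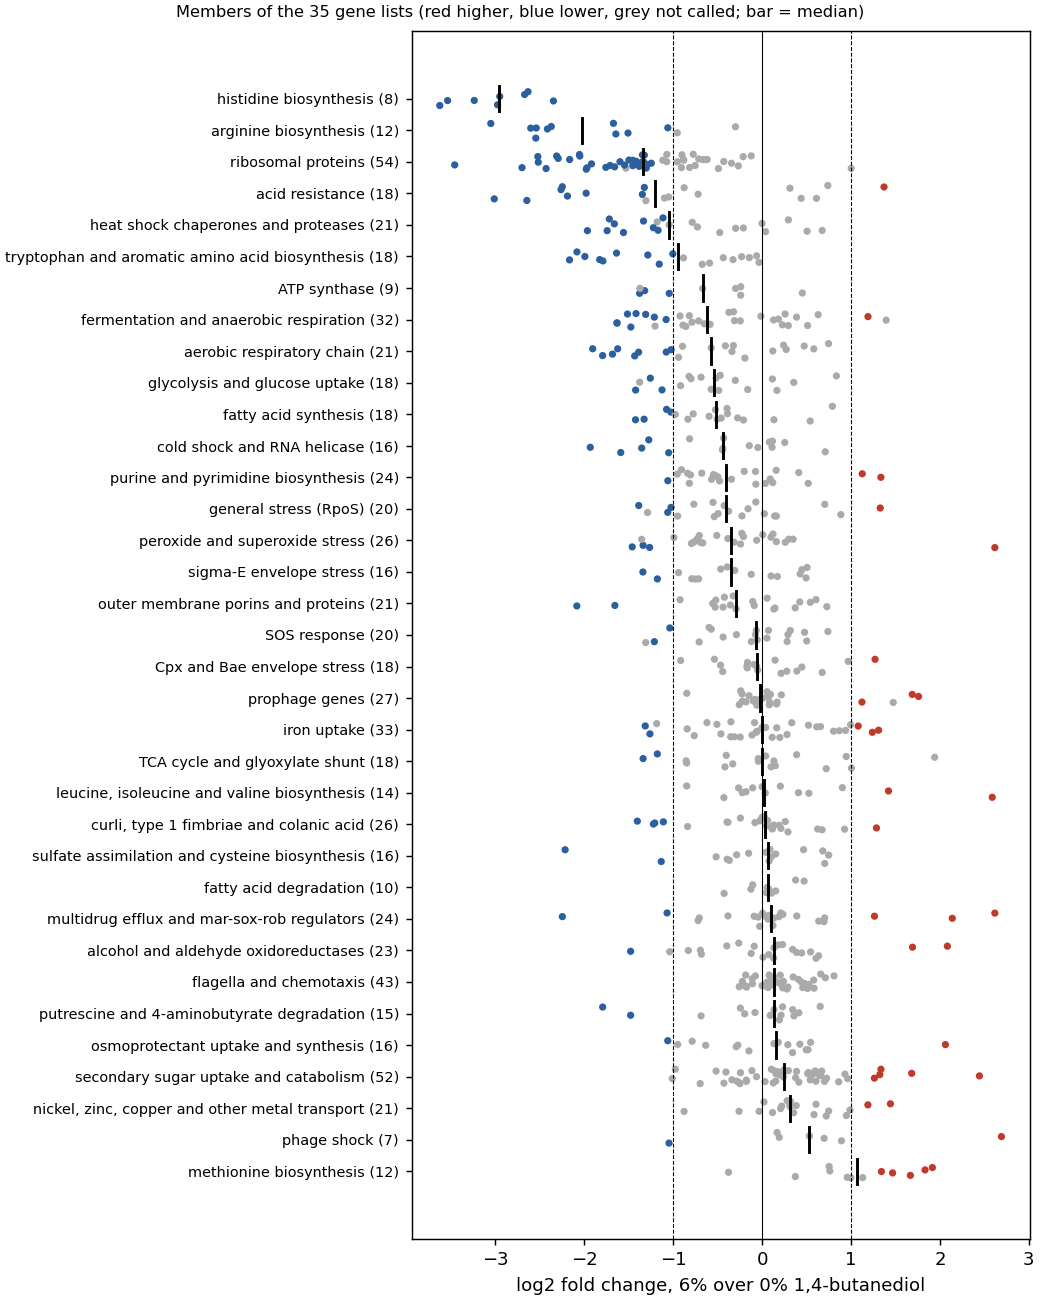
Log2 fold change (6% over 0% 1,4-butanediol) of each measured member of the 35 lists, with called rises in red, called falls in blue, other members in grey and the list median as a black bar; the number of measured genes follows each name. All 8 histidine members lie to the left of -1, 53 of 54 ribosomal protein members are below 0, and methionine biosynthesis has the highest median, 1.06.

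In all, camera placed 13 lists lower and 3 higher at an adjusted p under 0.05, and 11 of these 16 passed with fry in the same direction. Fry alone called 4 more lists: phage shock (adjusted p = 0.0063), efflux (0.013) and branched-chain biosynthesis (0.015) higher and outer membrane proteins (0.015) lower. With the correlation estimated per list from the 6 arrays, camera called none, and 4 had an unadjusted p under 0.05. The estimates for metal transport (-0.024) and secondary sugars (0.0035) were below the preset 0.01, yet both lists lost their call. Correlation within lists is therefore not the whole reason for the lost calls, since this setting has few degrees of freedom with 6 arrays. Of the 16, 11 passed in the same direction with slide as a block. Adjusted over the list alone, 4 peroxide, 4 glycolysis, 4 ATP synthase, 9 fermentation and 3 SOS genes were lower and 2 fermentation genes and 1 TCA cycle gene higher at least 2-fold; the counts of lists for which no such number is given were as over all genes. Median and mean differed in sign in the Cpx and Bae, sulfate, iron, putrescine, curli and fimbriae, and prophage lists, none of which passed the camera test. Leaving out 1 array turned the sign of the median in at least 1 fit for these lists and for the osmoprotectant, flagella, TCA cycle, branched-chain and fatty acid degradation lists.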

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

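The scanner gain and narrow-array settings were chosen after seeing the data; the others were planned. With slide as a block, 62 genes rose and 93 fell with or without the 2-fold threshold. The camera direction of the sulfate assimilation list reversed, from lower and not called (median 0.06) to higher (median 0.54, adjusted p = 0.012). The cause was not tested. Scaling to cysG, hcaT and idnT gave 141 higher and 618 lower calls, and 202 and 807 without the fold threshold, because it lowers every fold change by a constant. A 1.5-fold minimum gave 445 and 521, a 4-fold minimum 31 and 65, and treat against 1.5-fold 77 and 143 calls. Without the fold threshold, array weights gave 820 higher and 848 lower genes, leaving out the narrowest array of each group 707 higher, and the 3 arrays of equal gain, with a lone 6% array assumed to vary like the controls, 270 higher and 250 lower; the cause was not tested. Lists called lower numbered 8 after quantile normalization, 8 after cyclic loess, 8 without the dimmest genes and 7 at equal gain, against 13; the cause was not tested. Among the lists no longer called lower by camera after quantile normalization and cyclic loess were peroxide and superoxide stress (adjusted p = 0.13 and 0.16) and glycolysis (0.11 and 0.054). ATP synthase (0.16 and 0.20) and fatty acid synthesis (0.080 and 0.078) were others, and all of these also lost their call without the dimmest genes. With an estimated correlation camera called 0 higher and 0 lower (4 at an unadjusted p under 0.05), and fry called 6 higher and 9 lower. Leaving out each array in turn gave 187 to 367 higher and 239 to 380 lower calls, 215 to 652 and 263 to 615 without the fold threshold, and 3 to 4 higher and 9 to 14 lower lists; 21 of the 98 called named genes lost their call in at least 1 of these fits and none changed sign. The replicate block gave 239 and 312 calls, and 310 and 387 without the fold threshold. It ended 4 named calls (rseB, tpiA, atpA and fabG) and no list call, and the numbers did not pair the arrays: deviations from the group means of same-numbered arrays correlated, across genes, at r = 0.35, -0.45 and -0.28, and not every array correlated best with its own number. With slide as a block, 58 of the 98 called named genes were no longer called; that fit rests on 1 exposed array. On the 6% arrays 21.2% to 32.6% of genes, and on the 0% arrays up to 44.1%, lay within 2-fold of the random probes, where changes are least measurable.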

Other observations

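The gene groups in this paragraph and the slide tests below were chosen after the values were seen; the tests on level, chromosome position and other splits of the arrays were planned before their results. All 9 genes measured in the adjacent hya operon (hydrogenase 1) and app operon (cytochrome bd-II oxidase and a phosphatase) fell, with a median log2 fold change of -3.12, and all 9 fell with slide as a block. Of genes for glutamine synthesis, glutamine uptake and nitrogen regulation, the 8 picked (glnA, glnL, glnG, glnH, glnP, glnQ, glnK and glnB) fell, with a median of -2.06. Of related genes not picked, amtB had a log2 fold change of -0.82, glnD 0.29 and glnE 0.02, and none was called. The threonine biosynthesis genes thrA, thrB and thrC fell, with a median of -2.17, and 4 of 5 arginine uptake (art) genes fell, with a median of -1.94. Of these, artJ is also counted in the arginine biosynthesis list. In the other direction, the 5 genes of the biotin cluster bioA to bioD rose, with a median of 1.27 and all within 2-fold of the random probes at 0%, while bioH, elsewhere on the chromosome, was at 0.40 and not called. Another 5 adjacent genes of the CP4-6 prophage (ykfI, yafW, ykfG, yafX and ykfF) rose, with a median of 1.88. Of the manganese-dependent ribonucleotide reductase genes, 3 of 4 rose (nrdH, nrdI and nrdF), with a median of 1.25. Of 10 hyf genes, for hydrogenase 4, 4 rose, with a median of 0.79. At 0%, 4 of the 5 CP4-6 genes, 7 of the 10 hyf genes and nrdF also lay within 2-fold of the random probes, as did glnL, glnK and artJ at 6%. Counted with slide as a block, 5 gln, 2 thr and 3 art genes fell and 3 biotin, 3 CP4-6, 1 nrd and 0 hyf genes rose.

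Of 54 ribosomal protein genes, 31 fell. A compressed range of bright genes on the 6% arrays would lower other bright genes as much, but 10000 random lists matched on mean level had a median of -0.05 with a lower 2.5% bound of -0.36, against -1.34 for the list. On the 6% array of the controls' slide, the median was -1.12 and 51 of 54 members lay below the mean of the 3 controls. That argues against a slide difference as the whole cause, though it rests on 1 exposed array that is itself part of the fall. Lower gene copy number near the replication origin is argued against by non-ribosomal genes matched in distance to the origin, whose median was 0.0789 (95% of draws between -0.09 and 0.23). That the fall reflects exposure to butanediol is then a hypothesis, and a difference between cultures unrelated to butanediol stays open, because the labels call the arrays technical replicates.

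Of 20 genes on the histidine and arginine biosynthesis lists, artJ included, 8 and 10 fell, with a joint median of -2.54. Matched random lists had a lower bound of -0.62, which argues against range compression. On the controls' slide the median was -2.53 with 20 of 20 members below the mean of the 3 controls. That argues against a slide difference as the whole cause, though it rests on 1 exposed array that is itself part of the fall. Exposure to butanediol and an unrelated difference between cultures stay open, the latter untested.

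Of 21 heat shock genes, 9 fell, and the list had a median of -1.05, below the lower bound of -0.60 of matched random lists, which argues against range compression. On the controls' slide the median was -0.75 and 16 of 21 members lay below the controls, against 17 of 21 with a negative change over all arrays. The list passed camera with slide as a block (adjusted p = 4.0e-04), a test at the preset correlation whose call without the block was lost with an estimated one (adjusted p = 0.34 with an estimated correlation). A slide contribution stays open, because only 1 exposed array bears on it. The share of members below the controls' mean could also hardly be higher in a list of mixed signs.

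A copy number effect was also tested along the whole chromosome. If exposure lowered the copy number near the origin, fold changes would rise with distance from it. Across genes, which are not independent replicates, Spearman's rho without ribosomal protein genes was -0.15, the opposite sign. The 10% of genes nearest the origin had a median log2 fold change of 0.15 and the 10% farthest -0.06.

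The 6 arrays can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split gave 595 genes changed at least 2-fold and 968 at any size, against a highest other count of 0 for each (limma; at an unadjusted p under 0.05 the other splits gave 1 to 363 genes and the real one 1497). For both counts 1 of the 10 splits, the real one, gave as many. For the list tests the real split gave 16 lists and the highest other split also 16, so 3 of the 10 splits gave as many. Those other 2 splits set control replicates 1 and 3 together with 6% replicate 1 or with 6% replicate 2 against the rest. The first of them follows the slides as closely as the real split does, with 3 arrays of slide 1 against the other array of slide 1 and both of slide 2. The remaining 2 splits of that kind, which set 6% replicate 1 with control replicates 1 and 2 or with control replicates 2 and 3, gave 14 and 9 lists. With slide as a block, 11 of the 16 lists passed in the same direction.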
